A study of Homo sapiens with 8 samples.

How the data were processed

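The series compared MDA-MB-231 cells 48 h after transfection with 75 nM of a miR-148b precursor with cells given a negative control, on human whole-genome Agilent arrays with 1 dye, Cy3, with 4 arrays per group, per the labels. Images were read with Agilent Feature Extraction 10.5.1.1, per the labels' descriptions. The background treatment, the normalization and any probe filter are not given in the sources used here. The values used are the probe intensity values on a linear scale that the authors deposited, as 1 table of 33446 probes by 8 arrays with all columns used (0 columns left out). The arrays shared their highest value and had nearly the same quartiles, as between-array quantile normalization gives. Of the values under 1000, 99.6% were whole multiples of a hundredth divided by 22 (tolerance 0.01 of a step), against 7.73% for 23, a pattern that a mean over 22 arrays would leave. Normalization of this kind gives each array the same overall distribution and cannot show a shift of all genes. The table carries no background or detection flag, so no value could be called absent, and fold changes of dim probes are less reliable.

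Log2 was taken of the deposited values with a pseudocount of 0 and no new normalization. Empty cells were left empty, which concerned 2864 probes, each on at most 3 arrays, and in fits with more terms an effect was used only where the remaining arrays could separate it. Probes were named through GEO's platform annotation, with symbols updated by gene number from a RefSeq gene table of assembly GRCh38.p14. One gene was named for 24790 probes, several for 27 and none was listed for 8629, which stayed unnamed. No genome build belongs to these values and no coordinates are given. Each of 15971 genes was represented by its probe with the highest mean level.

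Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all probes or genes and a threshold of 0.05, and again at the thresholds of the series' design text, a 1.5-fold change and a rate of false discoveries of 16%. For 29 gene lists, camera was run with a preset correlation of 0.01 and again with an estimated one, and fry as a test of each list by itself. The result of 1 list is not reported here. Single fixed genes were tested by exact two-sided permutation of the arrays over 70 arrangements. Figures were drawn with matplotlib. The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 genes with the largest rise and the 12 with the largest fall past an adjusted p of 0.05 without overlap of the groups, filled up from genes past the series' thresholds in order of fold, then from those with the smallest p, as values only. As 0 genes passed either, the last step chose all 24. The rule always added ITGA5, ROCK1, PIK3CA, NRAS, CSF1, DNMT1 and COPZ1, and per list up to 4 members past the threshold, or else the 2 with the smallest p, which was the case in every list given here.

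The replicate numbers of the labels paired the arrays only in part. Deviations from the group means correlated over probes at 0.61, 0.59 and 0.66 between replicates 1, 3 and 4 of both groups, which match in code and plus mark. For replicate 2, whose arrays differ in both, the correlation was -0.50. The code numbers in the titles also paired the arrays in part: the 5 pairs of a control and a miR-148b array of the same code correlated at 0.61, 0.63, 0.22, 0.59 and 0.66. Control replicate 2 and miR-148b replicate 4, of codes 2 and 3 and both without a plus mark, correlated at 0.53. The code number took 60.9% of the variance, and code 1 with the plus mark took 73.6%. The code number alone thus does not hold all of the structure. The fit without a block, fixed in advance, gives the values of the report, and the fit with the code number as a block stands beside them where it changes a call. The code-number pairing was read from the titles, not stated in the labels as a shared batch.

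The tests were run on simulated data with the spread of the real arrays. With the code differences of the real arrays added, the fit without a block found 0, 5.97 and 51.5% of probes changed 1.5, 2 and 4-fold (67, 67 and 66 probes among 30582) at 0.05, and the fit with the code number as a block found 1.49, 38.8 and 66.7%. Without the code differences the fit without a block found 14.9, 41.8 and 81.8%. The interferon response list, shifted by -0.5 among 14858 genes, was found by camera with the preset correlation in 20 of 20 runs in both fits. With an estimated correlation and the code differences added, it was found in 0 of 20 runs without a block and in 20 of 20 with it. Without the code differences it was found so in 20 of 20 runs of both fits. In the real arrays this list had a median log2 difference of -0.74 between code 1 and the other codes, and code 1 holds more miR-148b than control arrays. The rates with the code differences added therefore belong to this list and not to lists in general. With the preset correlation and the code differences, unchanged lists were called in 6 of 540 tests without a block and in 1 with it. Without the code differences each fit called 1 of 540. The simulated noise was independent between genes and held no differences by the plus mark. Real lists had estimated correlations of 0.48 (histones) and 0.33 (interferon) without a block, and 0.46 and 0.028 with it. The simulated rates therefore do not carry over to lists whose members move together.

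Alternatives were another quantile normalization, median-centred arrays, leaving out the dimmest 33.3% or 50% of probes, an intensity trend in eBayes, array weights, the replicate number or code number as a block, the mean of a gene's probes, and leaving out each array in turn. Terms for code 1 and the plus mark, probes without empty cells, and leaving out the code 1 or plus arrays were added after seeing the data. The test of seed matches of miR-148b in 3 prime untranslated regions was not run, because no transcript sequence was used here.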

Results

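Gene expression was measured in MDA-MB-231 cells, a human breast cancer line of mesenchymal character, 48 h after transfection with a precursor of the microRNA miR-148b at 75 nM or with a negative control. MicroRNAs are short RNAs that lower the level or translation of messages carrying matching sites. The series holds 8 arrays of 1 dye channel, 4 per group, which the labels call biological replicates. Each array gave normalized intensities for 33446 probes, with medians from 370 to 404 and a shared highest value of 243058. Between 81 and 1038 probes per array had an empty cell, and these probes were mostly dim. The number of arrays limits the precision of every value.

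The sample titles also carry a code number and, on some arrays, a plus mark, whose meaning the labels do not give. Code 1 covers control replicate 1 and miR-148b replicates 1 and 2. Code 2 covers control replicates 2 and 3 and miR-148b replicate 3, and code 3 covers replicate 4 of each group. The plus mark stands on control replicate 3 and miR-148b replicates 2 and 3. The arrays separated by code 1 against the other codes, which took 48.3% of the variance, and by the plus mark, which took 25.3%, where the treatment took 12.3% and a random split of 4 against 4 would take 14.3%. Code 1 and the plus mark together took 73.6%, and 79.9% with the treatment added. The cancer-testis antigen gene MAGEA12 read 8256 ± 1619 (SD, n = 3) on the code 1 arrays and 165 ± 19.1 (SD, n = 5) on the others, in both treatment groups. The interferon-induced gene IFI27 read 184 ± 38.0 (SD, n = 3) on the code 1 arrays and 12606 ± 1866 (SD, n = 5) on the others. Code 1 holds 2 of the 4 miR-148b arrays and 1 of the 4 control arrays, so values with the code number as a block are given where they change a call. The plus mark is as uneven, on 2 of the 4 miR-148b arrays and 1 of the 4 control arrays, and that block does not remove it. Within code 1 only a miR-148b array carries it, and the 1 miR-148b array of code 2 carries it. Blocked and within-code values of codes 1 and 2 therefore stay mixed with the plus mark. Of the replicate numbers, only replicate 2 differs in code and plus mark between the groups.

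**Figure D1:**
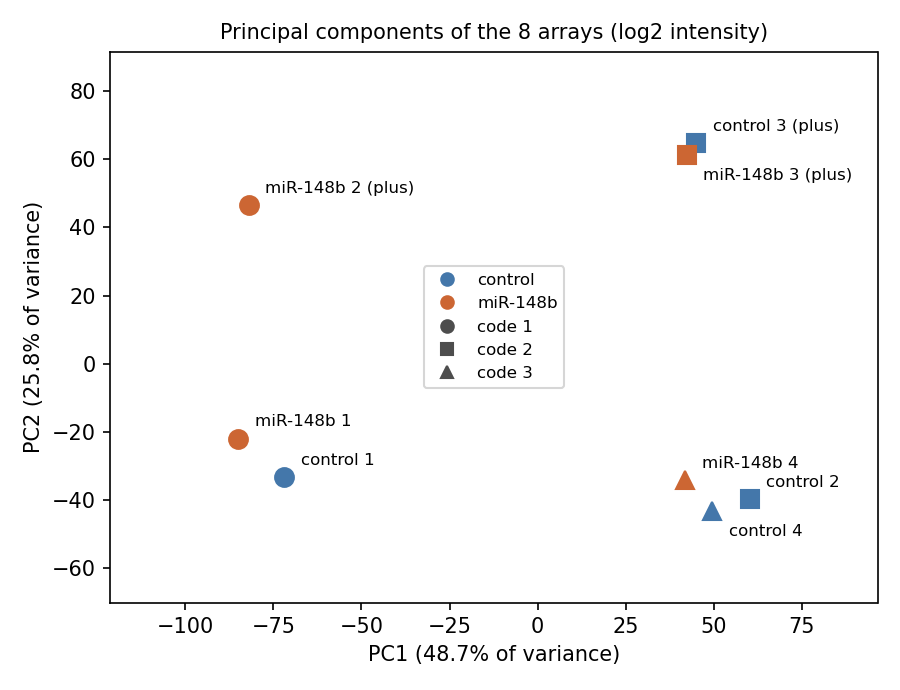
First and second principal components (axes, in log2 intensity units, with 48.7% and 25.8% of the variance) of the 8 arrays, coloured by treatment and shaped by code number. The 3 code 1 arrays lie at the left and the 3 arrays with a plus mark at the top, and the 2 treatments do not separate.

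**Figure D2:**
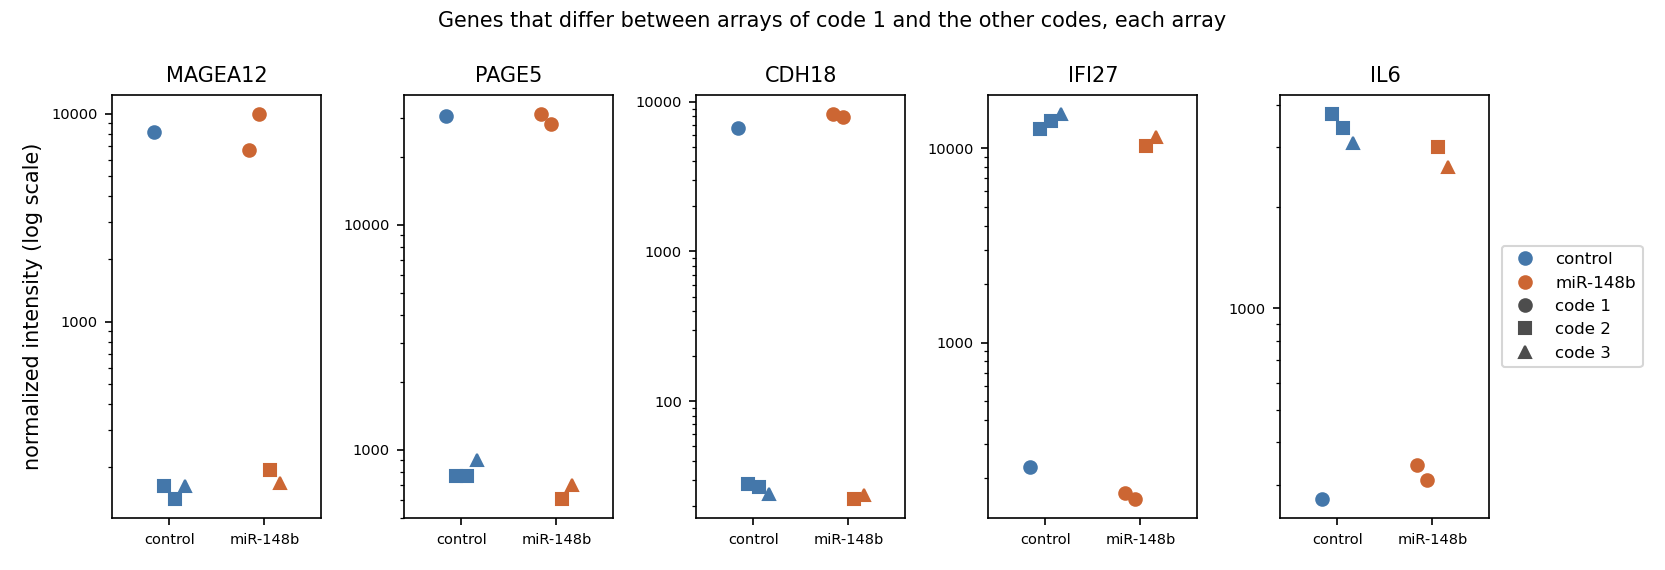
Normalized intensity (log axis) of 5 genes on each array, by treatment, with the code number as the symbol. MAGEA12, PAGE5 and CDH18 read higher and IFI27 and IL6 lower on the 3 code 1 arrays than on the other 5, in both treatment groups.

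The first comparison asked which genes miR-148b modulated. The genes with the smallest p-values below control were led by TMEM54, a membrane protein gene, at 3343 ± 209 in control and 1723 ± 102 with miR-148b (SD, n = 4 each), a log2 difference of -0.96 (SE 0.13). CTSA, which encodes the lysosomal protein cathepsin A, read 15258 ± 2187 in control and 7186 ± 1324 with miR-148b (SD, n = 4 each). TXNIP, an inhibitor of thioredoxin, read 27111 ± 4894 in control and 14725 ± 1684 with miR-148b (SD, n = 4 each), and LAMB2, a laminin chain, 16276 ± 1432 and 10353 ± 1049. Above control, the secreted pattern recognition protein gene PTX3 read 12359 ± 1017 in control and 21740 ± 2834 with miR-148b, and CDK6, a kinase of the G1 phase, 10167 ± 1827 and 17900 ± 2710 (SD, n = 4 each). None of these single genes passed the adjustment over all genes.

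Among the 12 genes below control that the fixed rule named, AHNAK2 had a log2 difference of -1.10 and FAM234A of -0.78. WASHC2C and WASHC2A, near-identical members of a complex that sorts endosomes and whose probes may not tell them apart, were at -0.73 and -0.75. HLA-DRB5, an MHC class II chain of a family of close relatives, was at -0.91, GNPDA1, an enzyme of glucosamine metabolism, at -0.89, CYTH4 at -0.69 and the dim olfactory receptor pseudogene OR5P1P at -1.18. The other probe of CYTH4, a dim one with an empty cell on miR-148b replicate 2, was at 0.30. Among the 12 genes above control, ERLIN2, a protein of the endoplasmic reticulum, was at 0.78, GNA13, a G protein subunit, at 0.80, CCNC, which encodes cyclin C, at 0.74 and ENTPD7, a nucleotidase, at 0.78. The zinc finger genes ZNF208, ZNF678, ZNF141 and ZBTB34 were at 1.11, 0.89, 0.81 and 0.71, ANKRD46 at 0.87 and ARMC1 at 0.72. In all 24 of these genes the 4 miR-148b arrays lay on one side of the 4 control arrays. The same sign of the difference within codes 1, 2 and 3 follows from that and is no further check. They were picked by their p-values, so this separation is partly a result of the choice.

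**Figure D3:**
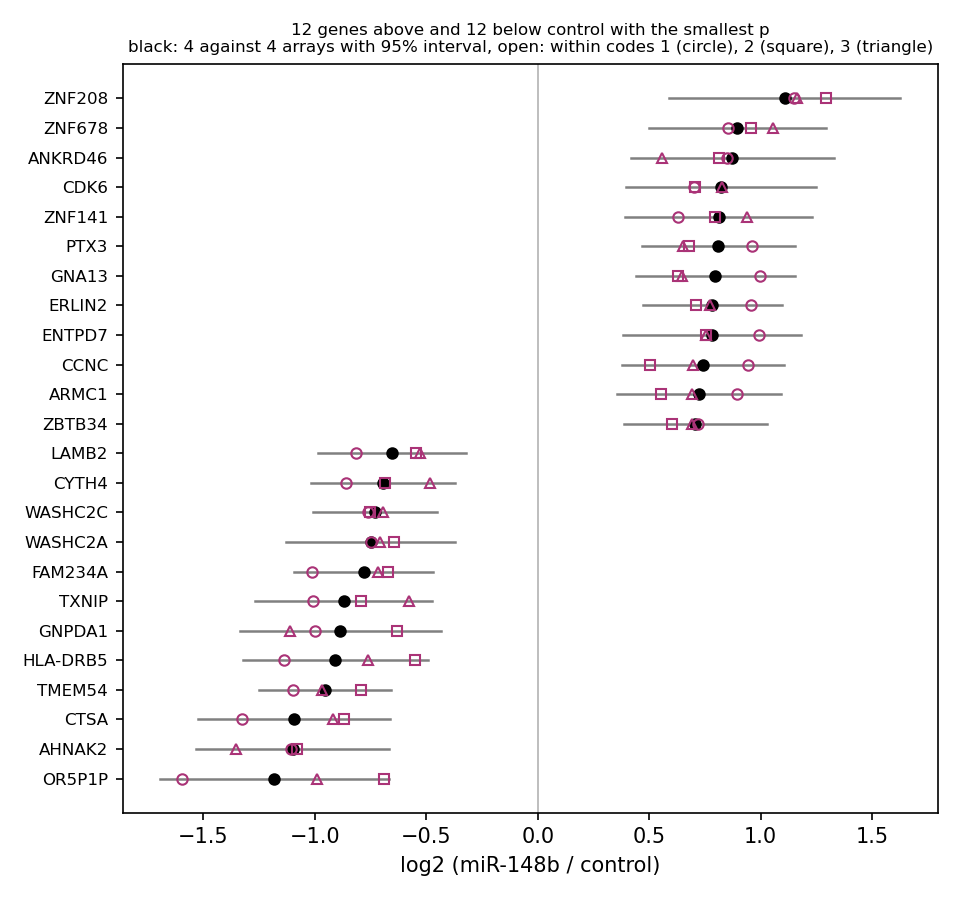
Log2 difference between miR-148b and control (horizontal axis) of the 12 genes above and 12 below control with the smallest p-values, as black points with 95% intervals over 4 arrays per group, and within each code as open symbols. Differences lie between 0.65 and 1.18 in size. The within-code values keep the sign of the black points, as they must where the groups do not overlap.

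In the limma test, 0 of 33446 probes and 0 of 15971 genes passed an adjusted p of 0.05, with smallest adjusted p of 0.908 and 0.847. At an unadjusted threshold of 0.05, 1431 probes passed, which is 4.28% of them, 715 above and 716 below control, and so did 858 genes. Among the 14825 genes with a value on every array, 593 (4.00%) had groups without overlap, 235 above and 358 below control, where chance gives 2.86% for unstructured arrays. In these arrays 8 others of the 35 splits into 4 and 4 gave as many such genes or more, up to 2193, each with all 3 code 1 arrays or all 3 plus arrays on one side, so 2.86% is no measure of chance for this count. The series' design text states 129 genes, 49 higher and 80 lower, past a 1.5-fold change with a rate of false discoveries of 16%, with the tool not given in the sources used here, while the same thresholds passed 0 probes in the limma test. With the code number as a block, 0 probes passed either threshold, and 3236 (9.68%) passed the unadjusted one. Of the 18 splits that keep the number of arrays of each code per group, 3 gave as many, the real split included, with 6482 the highest other. This count therefore does not set the treatment apart. With terms for code 1 and the plus mark, chosen after seeing the data, 199 of 16707 probes above the median level passed the thresholds of the series, 113 higher and 86 lower, but 0 passed 0.05. They include the probes of 18 of the 24 named genes, of which 19 were in this fit. Those genes were picked by p-value on the same arrays, so their passing is no further support.

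The second comparison concerned genes fixed in advance because the study or earlier work ties them to miR-148b. ITGA5, the alpha 5 integrin subunit of the fibronectin receptor, read 624 ± 120 in control and 375 ± 52.7 with miR-148b (SD, n = 4 each), a log2 difference of -0.72 (SE 0.19). ROCK1, a serine/threonine kinase, read 1807 ± 152.3 and 1400 ± 77.4 (SD, n = 4 each), a log2 difference of -0.37. All 4 miR-148b arrays lay below all 4 control arrays for both genes, which gives the smallest p that 70 arrangements allow, 0.0286 in an exact two-sided permutation test, or 0.0714 after Benjamini-Hochberg adjustment over the 5 genes. Both fell when adjusted over the list alone of the study's reported targets (2 of 3 measured, limma adjusted p = 0.0149 and 0.0379), which the study chose on these samples and is not independent evidence, and not over all genes (0.847). A second, dimmer probe of ROCK1 did not read lower, at 0.13.

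CSF1, the macrophage colony-stimulating factor, read 416 ± 55.3 in control and 329 ± 44.5 with miR-148b (SD, n = 4 each) at its brighter probe, a log2 difference of -0.34 with overlapping groups, while its dimmer probe was at -0.80. DNMT1, the maintenance DNA methyltransferase, was at -0.46 with overlap and at -0.59 with the code number as a block. With that block its limma p was 0.0151 unadjusted and 0.330 adjusted over all genes. COPZ1, the gene whose intron encodes miR-148b, was at -0.22 (SE 0.16). In exact permutation tests, which ignore the codes, CSF1, DNMT1 and COPZ1 had p of 0.0857, 0.0571 and 0.200, or 0.107, 0.0952 and 0.200 adjusted over the 5 genes. PIK3CA and NRAS were not analysed here.

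**Figure D4:**
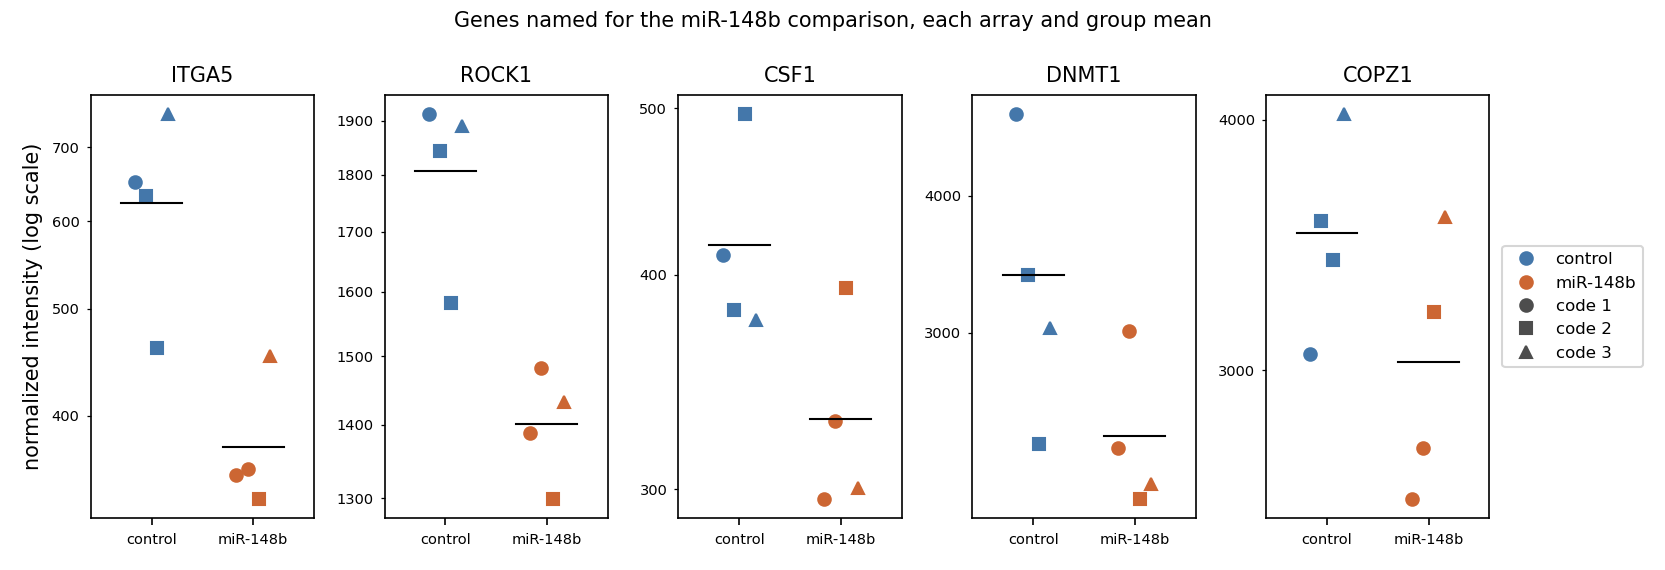
Normalized intensity (log axes that do not start at 0) of ITGA5, ROCK1, CSF1, DNMT1 and COPZ1 on each array, by treatment, with the code number as the symbol and the group mean as a line. For ITGA5 and ROCK1 all 4 miR-148b arrays lie below the 4 control arrays, and for the other genes the groups overlap.

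The third comparison asked whether 29 gene lists fixed in advance moved together, by the camera test of limma over 14825 genes. The interferon response, MHC class I, lysosome, leukocyte and histone lists were lower with miR-148b in camera with the preset correlation, but not with an estimated one, and fry, which tests each list by itself, passed none of them without a block (adjusted p = 0.377, 0.323, 0.342, 0.323 and 0.542). With the code number as a block fry passed the interferon list (0.0127) and not the others (0.0501, 0.0501, 0.155 and 0.266). The interferon response list had a median log2 difference of -0.48 over 36 genes, with 34 below control, 0 past the threshold over all genes and 0 adjusted over the list alone. UBE2L6, a conjugating enzyme of the ubiquitin-like protein ISG15, read 1169 ± 34.0 and 853 ± 77.9, and IFITM2, a membrane protein that restricts virus entry, 11321 ± 430 and 8745 ± 301 (SD, n = 4 each, control and miR-148b). The list of MHC class I antigen presentation had a median of -0.33 over 18 genes, with 16 below control, among them the chaperone PDIA3 at -0.93 and the peptide loading factor TAPBP at -0.59. The lysosome and proton pump list had a median of -0.21 over 24 genes, 17 of them below control, where CTSA fell when adjusted over the list alone (0.00815) and the pump subunit ATP6V0D1 was at -0.41. The leukocyte marker list was at -0.52 over 11 genes, with 13 of 15 measured below control, among them the lysosomal protein CD68 at -0.57 and the lipopolysaccharide receptor CD14 at -0.72. The measured genes outside that median had an empty cell. As the samples are a breast cancer line, the list is no measure of leukocytes here. The replication histone list was at -0.21 over 24 genes, 18 below control, with H2AC6 at -0.44 and H2BC9 at -0.38.

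The interferon response, MHC class I, lysosome, leukocyte and histone lists had adjusted p of 1.17e-04, 0.00123, 0.00565, 0.0211 and 0.0328 in limma's camera test, and none kept its call with an estimated correlation (adjusted p = 0.548, 0.548, 0.548, 0.524 and 0.655). In the fit without a block, apart from the study's targets and CTSA, 0 genes of the lists given here passed when adjusted over the list alone. With the code number as a block, further genes passed adjusted over the list alone, not over all genes: CDK6 (limma adjusted p = 0.0148) and TDG (0.0340), ITGA5 (0.0194) and ITGB4 (0.0458) of the integrins, IL11 (0.00457) of the colony-stimulating factors and chemokines, COL5A2 (0.0472), DUSP5 (0.0488) and AGR2 (0.0187). With that block IL11 was at 1.01, against 0.50 without it, ITGB4 at -0.73 against -0.48 and AGR2 at -0.57 against 0.27. Of the interferon list, 24 of 36 measured genes were also lower on the code 1 arrays than on the others, and so were 8 of 18 MHC class I and 9 of 24 lysosome genes. With the code number as a block, the median of the interferon list was -0.24, with values of -0.28, -0.18 and -0.25 within codes 1, 2 and 3, and that of the MHC class I list -0.26. The list of the study's reported targets fell as well (ITGA5, ROCK1 and CSF1, median -0.37, camera adjusted p = 0.00330, or 0.326 with an estimated correlation), and it passed fry without a block (0.00185) and with it (0.00797). The leukocyte list lost its call without control replicate 2 (adjusted p = 0.0543), miR-148b replicate 2 (0.0735) or miR-148b replicate 3 (0.0997), the lysosome list without miR-148b replicate 1 (0.0597), and the histone list without control replicate 1 (0.424), control replicate 4 (0.165), miR-148b replicate 2 (0.266) or miR-148b replicate 3 (0.568). With terms for code 1 and the plus mark the leukocyte (0.0817, median -0.19) and histone (0.467, median -0.09) lists lost their calls. The interferon (1.19e-06, median -0.30), MHC class I (5.56e-04, median -0.36) and lysosome (0.0312, median -0.14) lists kept theirs with these terms, but not with an estimated correlation (0.432 each). Without the code 1 arrays the lysosome (0.0787) and histone (0.232) lists lost their calls. Without the plus arrays the leukocyte (0.201) and histone (0.742, median -0.0094) lists lost theirs, and the histone list also with median-centred arrays (0.0522) and the mean of a gene's probes (0.250).

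The sterol biosynthesis, G1 to S, G2 and mitosis and DNA methylation lists were higher with miR-148b in camera with the preset correlation, but not with an estimated one, and fry passed none of them without a block (adjusted p = 0.294, 0.401, 0.377 and 0.377) or with it (0.156, 0.149, 0.283 and 0.249). The sterol biosynthesis list had a median of 0.21 over 23 genes, 18 above control, with the demethylation enzyme MSMO1 at 891 ± 198 in control and 1442 ± 197 with miR-148b and SQLE, which encodes squalene epoxidase, at 3287 ± 1118 and 5352 ± 924 (SD, n = 4 each). The list of the G1 to S transition had a median of 0.18 over 29 genes, 20 above control, with CDK6 at 0.82 and the replication licensing gene CDC6 at 0.48. The G2 and mitosis list was at 0.08 over 29 genes, 23 above control, with BIRC5, the survivin gene, at 0.43 and HMMR at 0.36. The DNA methylation list was at 0.30 over 16 genes, 12 of 17 measured above control, with the glycosylase TDG at 7689 ± 1635 and 14197 ± 3200 (SD, n = 4 each) and GADD45A at 0.50. Its methyltransferases went both ways, with DNMT1 at -0.46 and, chosen after their values were seen, DNMT3B at 0.99 and DNMT3A at 0.52. In the fit without a block 0 members of these lists passed the threshold over all genes or adjusted over the list alone.

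In limma's camera test these lists had adjusted p of 0.00330, 0.00339, 0.0232 and 0.0115, and with an estimated correlation adjusted p = 0.524, 0.548, 0.548 and 0.548. The G2 and mitosis list lost its call with the code number as a block (adjusted p = 0.0866, median 0.09), without control replicate 3 (0.0502) and without miR-148b replicate 2 (0.192), and the DNA methylation list without miR-148b replicate 2 (0.0528). With terms for code 1 and the plus mark the G1 to S list lost its call (0.132, median 0.07), as it did without the plus arrays (0.255), and the sterol list lost it without the code 1 arrays (0.0513, median 0.09). The G2 and mitosis list also lost its call with those terms (0.255), with the code number and plus mark (0.258), without the code 1 arrays (0.185), without the plus arrays (0.446) and without the dimmest 50% of probes (0.0598). The DNA methylation list lost its call without the code 1 arrays (0.0884, median 0.10), without the plus arrays (0.101) and with the code number and plus mark (0.0720).

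**Figure D5:**
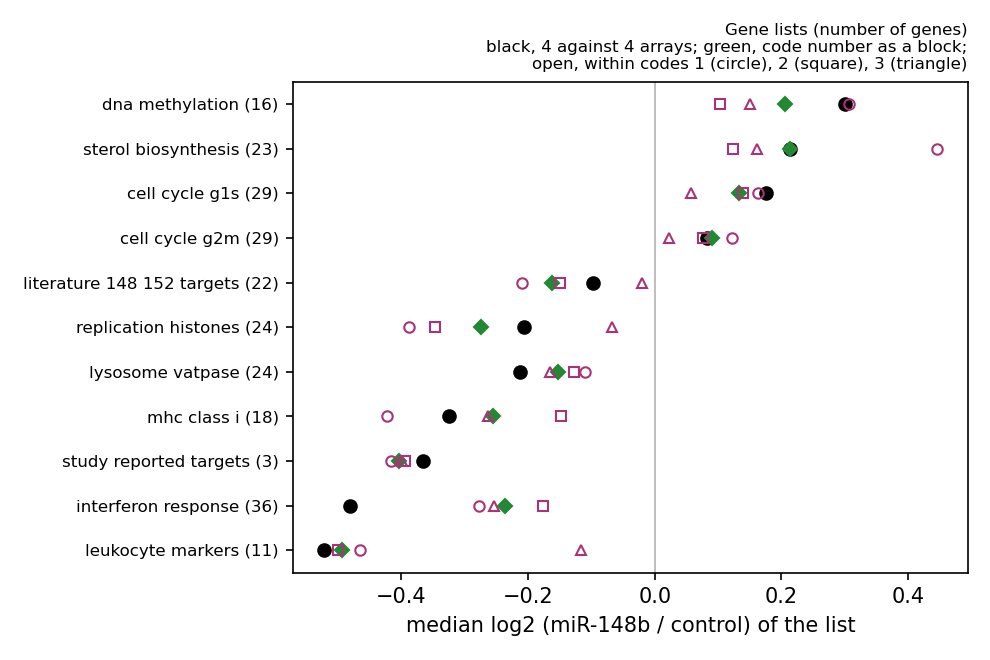
Median log2 difference between miR-148b and control (horizontal axis) of the 10 gene lists past the camera threshold and of the list of literature targets, with the number of genes, as black points over 4 arrays per group, green diamonds with the code number as a block and open symbols within codes. The interferon list lies at -0.48 and at -0.24 with the block.

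The following lists did not pass camera. With the code number as a block, fry passed the luminal marker list (adjusted p = 0.00797, median -0.20) and the oxidative phosphorylation list (0.0389, median -0.11), which it did not without the block (0.694 and 0.323). Literature targets of the miR-148 family had a median of -0.10 over 22 genes (camera adjusted p = 0.364), with 12 below and 10 above control, among them the glucose transporter SLC2A1 at -0.41 and GADD45A at 0.50. With the code number as a block their median was -0.16 (camera adjusted p = 0.242), with 15 below and 7 above control. With terms for code 1 and the plus mark it was -0.20 (camera adjusted p = 0.117). The integrin list was at -0.10 (ITGA3 at -0.45), focal adhesion at -0.15 (PTK2 at 0.56, LIMS2 at -0.46) and matrix proteases at -0.26 (MMP15 at -0.62, CTSD at -0.87). With the code number as a block the matrix protease list was at -0.045, and at -0.015, 0.010 and -0.057 within codes 1, 2 and 3. Signalling lists were at 0.04 for PI3K and AKT (IRS1 at 0.37, PIK3R1 at 0.97), 0.10 for RAS and MAPK (DUSP5 at 0.46, SOS2 at -0.30) and -0.14 for colony-stimulating factors and chemokines (CXCL5 at 0.28). The lists of the epithelial junction (JUP at -0.53, CLDN3 at -0.39), mesenchymal genes (COL5A2 at 0.74), p53 and apoptosis (TP53I3 at -0.44) and hypoxia and glycolysis (ALDOA at -0.37) had medians of -0.04, -0.14, -0.0068 and -0.0048. In the p53, epithelial junction, hypoxia and luminal marker lists the median, the mean and the camera test differed in sign.

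The unfolded protein response list was at 0.10 (PSAT1 at 0.64), oxidative phosphorylation at -0.08 (COX6B1 at -0.29, NDUFV1 at -0.39), ribosomal proteins at 0.03 (RPL22 at 0.33, RPS2 at 0.14) and microRNA machinery at -0.11 (AGO1 at -0.27, TNRC6C at -0.32). Of the markers of other cell types, luminal breast markers had a median of 0.03 (CDH1 at 0.82, GREB1 at -0.50, both dim). CDH1 was at 2.53, -0.02 and 0.12 within codes 1, 2 and 3, so its value rests mostly on code 1, where control replicate 1 read 17.9. Fibroblast markers were at -0.47 (THY1 at -0.49 and the dim COL3A1 at 0.65). Their median was -0.23 with the code number as a block and -0.045 with terms for code 1 and the plus mark. The cancer-testis list had a median of 1.03 (MAGEA10 at 0.77 and SSX2 at -0.38), and of -0.01 with the code number as a block, and 10 of its 16 measured genes were higher on the code 1 arrays. These 3 lists had camera adjusted p of 0.911, 0.173 and 0.174. Leaving out 1 array brought further lists past the threshold: cancer-testis without control replicate 1 (adjusted p = 0.00591) or miR-148b replicate 3 (0.0158), RAS and MAPK without control replicate 1 (0.0414), focal adhesion without control replicate 3 (0.0447), colony-stimulating factors without miR-148b replicate 3 (0.0262) and fibroblast markers without miR-148b replicate 4 (0.0324). Focal adhesion also passed without the plus arrays (0.0117, median -0.27), fibroblast markers with array weights (0.0466) and cancer-testis with the replicate number as a block (0.0430).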

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

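Of 207 groups of 4 arrays tested over the named genes, gene lists and empty cells, 14 had an array far from the other 3 of its group, where chance alone gives about 1 in 20. That rate assumes alike arrays, while control replicate 1 is the only control of code 1 and control replicate 3 the only one with a plus mark. All tests in the paragraph on code 1 were chosen after the result was seen.

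For single genes, control replicate 3 stood high for ARMC1 (1556 against 1142 to 1212 on the other 3 arrays), IRS1 (4020 against 3086 to 3152), BIRC5 (40423 against 24069 to 26570) and SQLE (4954 against 2559 to 2843). Control replicate 1 stood high for PTK2 (2572 against 1485 to 1540). Control replicate 2 stood low for the dim OR5P1P (19.5, where the highest of the other 3 was 23.6). Among the miR-148b arrays, replicate 4 stood high for DUSP5 (4244 against 3292 to 3360), replicate 2 for MSMO1 (1738 against 1332 to 1355), and replicate 1 low for the dim GREB1 (18.8 against 30.7 to 31.8). For gene lists, as medians relative to each gene's mean on the log2 scale, control replicate 4 stood high for oxidative phosphorylation (0.17). Control replicate 1, the control array of code 1, stood high for the cancer-testis list (2.02 against -1.47 to -1.11) and RAS and MAPK (0.29), and low for MHC class I (-0.17 against 0.30 to 0.32) and p53 and apoptosis (-0.15).

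The separation of the 3 code 1 arrays took 48.3% of the variance, more than any of the other choices of 3 of the 8 arrays, of which the highest took 31.5% (1 of 56 choices as large), so a random choice of arrays is argued against. Noise of dim probes is argued against by the share in the probes above the median level, 49.6%. For scaling of the arrays, code 1 took 50.6% of the variance of the ranks of the probes within each array. The deposited arrays had nearly the same quartiles and highest value, so the ranks follow the values closely. A share near that of the values was given in advance, and the ranks cannot decide on scaling. A minority of other cells mixed into the code 1 samples is argued against by 48 genes over 16-fold lower in code 1, since added cells dilute the resident messages only by their share. A different culture, passage or derivative of the line, or cells of another line, may lie behind code 1, and a difference between culture batches stays open too. These were not tested, and the design names no group that would give a biological explanation.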

How the results depend on the processing

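The alternatives with terms for the plus mark, with probes without empty cells, and without the code 1 or plus arrays were chosen after the data were seen, and for values that moved or reversed here the cause was not tested, except for CYTH4. Of 102 alternatives of counts, 90 stayed within 1.5 times the reported count, with 0 probes and 0 genes past 0.05 in limma with the replicate number as a block (2543 probes at an unadjusted 0.05, 11 gene lists) and with the code number as a block (3236 probes). Terms for code 1 and the plus mark gave 17 genes past 0.05 and 200 probes past the series' thresholds with an intensity trend, and 37 genes and 199 probes on the probes above the median level. The 10 gene lists past camera's threshold became 0 with an estimated correlation, 6 with terms for code 1 and the plus mark (6 with a trend, 6 on the brighter probes), 6 with the code number and plus mark, 5 without the code 1 arrays, 6 without the plus arrays, and 6 to 11 when 1 array was left out, with 6 without miR-148b replicate 2. Of 754 alternatives of the lists, 643 kept direction and call, 52 lost and 9 gained a call and 50 reversed, of which 0 passed the threshold. Of 1833 alternatives of named genes, 1811 kept direction and call, 19 gained a call and 3 reversed, all with the mean of a gene's probes: RPS2 to -0.011, also over probes without empty cells (-0.011), and CYTH4 to 0.31. The value of CYTH4 comes from its construction, since the dim probe is empty on miR-148b replicate 2, whose mean then rests on the bright probe alone, and over probes without empty cells CYTH4 was at -0.69. For the 24 genes, 587 of 588 alternatives kept the sign, with CYTH4 the exception. The reversed lists follow as medians. The luminal list read -0.0065 after quantile normalization, the PI3K list -0.040 without the dimmest 50% of probes, the epithelial junction list 0.030 with array weights and the literature targets 0.016 with the mean of probes and 0.0047 with that of probes without empty cells. With the code number as a block, the luminal list read -0.20, RAS and MAPK -0.0031, p53 0.036, the mesenchymal list 0.061, cancer-testis -0.013 and ribosomal proteins -0.028. With terms for code 1 and the plus mark, without or with a trend, RAS and MAPK read -0.016, p53 0.047, the mesenchymal list 0.054 and the luminal list -0.27. On the brighter probes these terms gave -0.014 for RAS and MAPK, 0.037 for p53, -0.069 for cancer-testis and -0.27 for the luminal list. The code number with the plus mark gave -0.037 for RAS and MAPK, 0.042 for p53, 0.095 for the mesenchymal list, -0.036 for cancer-testis, -0.0022 for ribosomal proteins and -0.21 for the luminal list. Without the code 1 arrays p53 read 0.054, cancer-testis -0.030, ribosomal proteins -0.010 and the luminal list -0.18. Without the plus arrays p53 read 0.023, the mesenchymal list 0.012 and the luminal list -0.0022. When 1 array was left out, the medians ranged from -0.056 to 0.026 for hypoxia, -0.046 to 0.020 for p53, -0.11 to 0.12 for the luminal list, -0.24 to 0.027 for the mesenchymal list, -0.12 to 0.042 for the epithelial junction and -0.024 to 0.066 for ribosomal proteins. The seed match test was not run, and the share of lower genes among called genes has no value with 0 genes called. The table holds no background level, so what signal over background limits stays open.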

Other observations

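The gene names in the next paragraph were chosen after their values were seen. Of the tests in this part, those of the uneven spread of code 1 and of a single array, the counts of splits for results of 0, the splits that keep the codes for the interferon list and the count of distinct contrasts were chosen after the result was seen, as were the fit with terms for code 1 and the plus mark and the comparison of code 1 with the other codes.

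With treatment and plus mark as terms, 5760 of 15964 genes differed between the 3 code 1 arrays and the other 5 in limma at an adjusted p of 0.05, 2749 higher and 3011 lower in code 1. Cancer-testis genes, normally silent outside the germ line, rose in code 1: 10 of 16 measured, 7 of them over 16-fold. PAGE5 read 29900 ± 1646 (SD, n = 3) against 747 ± 108 (SD, n = 5), and MAGEA12 was 49.0-fold higher, with probes that can read relatives in these families. The trefoil factor gene TFF1, known from luminal breast cells, read 10567 ± 1406 (SD, n = 3) against 386 ± 133 (SD, n = 5), and the cadherin gene CDH18 7615 ± 850 (SD, n = 3) against a dim 25.0 ± 2.38 (SD, n = 5). Interferon genes fell, 24 of 36 measured, with IFI27 64.4-fold lower. IL6 was 10.1-fold lower in code 1, IL24 26.3-fold, the long noncoding RNA UCA1 24.8-fold, the collagenase gene MMP1 3.31-fold and CD44 2.38-fold, while the chemokine receptor gene CXCR4 was 2.99-fold higher. Between arrays with and without the plus mark 2151 of 15873 genes differed. The effect of miR-148b differed between code 1 and the other codes in 0 of 15864 genes (limma interaction term, smallest adjusted p = 0.540, 601 genes at an unadjusted 0.05). Control replicate 1 is the only control array of code 1, so the test had little power and does not show that the effects were alike.

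After terms for code 1 and the plus mark, and over genes with probes above the median level and no empty cell, 37 genes passed an adjusted p of 0.05 for miR-148b in limma, 18 higher and 19 lower, and 10 of them are among the 24 named genes. Outside that rule, and picked after their values were seen, the cytokine gene IL11 rose by 0.97 (SE 0.12, log2), the transcriptional repressor gene REST by 0.85 and the zinc finger gene HIC2 by 0.79, while the semaphorin and VEGF coreceptor NRP1 was at -0.63, the ependymin-related gene EPDR1 at -0.81 and the interferon-induced GBP3 at -0.65. Chance could not be excluded for these counts: 3 of the 35 splits of the 8 arrays into 4 and 4 gave as many genes (37 for the real split, 51 the highest other), and 3 gave as many probes past the series' thresholds (199, against 1711). With these terms the 35 splits come down to 32 contrasts, of which 2 gave as many genes and 3 as many probes. The contrast with 51 genes sets control replicate 2 alone against the rest and that with 1711 probes miR-148b replicate 1 alone, so neither is a comparison of 4 arrays with 4. Among the other contrasts of more than 1 array, 0 genes was the highest count against 37, but 233 probes the highest against 199. These genes are a hypothesis about miR-148b for an experiment with balanced codes.

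For the counts of 0 probes past 0.05, 0 genes past 0.05 and 0 probes past the series' thresholds, the splits say nothing about chance, since any split gives at least 0 (35 of 35), and the highest others gave 692, 247 and 3384. All came from the split that sets the 3 plus arrays and miR-148b replicate 1 against the rest, which points to the structure of the arrays.

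The number of gene lists past the camera threshold, 10, was above that of every other split (1 of 35 as large, highest other 9). These 10 include the list of the study's reported targets, which the study chose on these samples. The margin of 1 list is therefore no independent evidence against chance, and the splits ignore the codes. Leaving out 1 array gave 6 to 11 lists and an estimated correlation 0. Among the splits that keep the codes as in the design, with the code number as a block, the real split gave 9 lists and the highest other 5 (1 of 18), which are too few splits for a share under 0.05. These 9 also include the study's own list. For the interferon list alone chance could not be excluded, since 7 of the 35 splits gave a p as small (real 5.39 and highest other 8.75, as the negative log10 of p). Those splits ignore the codes, and the 18 that keep them, too few for a share under 0.05, gave 6.13 for the real split and 5.08 as the highest other toward lower values.

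The lower interferon list with miR-148b could come from the uneven spread of code 1, whose arrays are low in this list. Against that as the whole source, the median with the code number as a block was -0.24 and below 0 within every code, with an adjusted p of 2.17e-05 in limma's camera test, although it was -0.48 without the block and the list did not pass with an estimated correlation after adjustment over the lists (adjusted p = 0.361). With terms for code 1 and the plus mark, the median of the interferon list was -0.30 (camera adjusted p = 1.19e-06, or 0.432 with an estimated correlation). Over the alternatives that change 1 choice and the added fits, its adjusted p ranged from 2.64e-07 to 0.548. A single array is argued against by a median of -0.32 at the nearest to 0 when any 1 array is left out. Of the 34 members not in the MHC class I list, 30 were lower with the block, with a median of -0.24. An effect of miR-148b and of the transfected RNA on interferon genes stay open as hypotheses, since the control RNA is the only other transfection here.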
